A study of Mus musculus with 57 samples.

How the data were processed

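The starting point was the table of deposited counts, 55401 gene identifiers by 57 libraries, which the authors made from polyA RNA. Their processing notes name FastQC, MultiQC, Trimmomatic, HISAT2, SAMtools, HTSeq, DESeq2 and edgeR and the build mm10, without versions or an annotation release. No reads were aligned or recounted here. The unit is counts, taken as whole numbers of reads per gene. Days 3 and 5 and the Z3KO libraries were sequenced at CNAG (19 libraries, 28348055 to 46938618 counts) and all others at Macrogen (38 libraries, 12911654 to 23838309 counts).

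Symbols and mm10 positions came from GENCODE M21. Of the identifiers 55141 matched it without the version suffix and 54349 with it, and 106 symbols are shared by more than 1 identifier. Within libraries of a group, correlations of log CPM were 0.964 or higher.

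Genes were filtered with filterByExpr and scaled by TMM in edgeR 4.0.16, and tested with the quasi-likelihood F test (R 4.3.3, limma 3.58.1). Comparisons were fitted in sets sharing day and experiment: day 0, days 3 and 5 together, day 6, the second differentiation, the FKBP lines, and Z3KO with WT of day 0. There were 11 comparisons of 2 groups, 7 interactions and 3 background contrasts of WT or DMSO groups. P values were adjusted by Benjamini and Hochberg within each comparison, and a call is an adjusted p below 0.05. The standard error is the absolute log2 fold change over the square root of F. CPM come from the cpm function of edgeR with the TMM-scaled library sizes of each fit. CPM of single libraries, of Rpl17 and Col4a1, and those marked so in the text are instead scaled over all 57 libraries. Where the lower group held fewer than 4 counts in all, the fold change was replaced by a bound or a ratio. With 0 counts the bound sets the lower group to 3 counts in its smallest library. With 1 to 3 counts the ratio is printed with its 95% interval. These bounds and intervals cover counting error only, and reads duplicated by PCR could not be removed without molecular barcodes.

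Gene lists were fixed before testing. The lists reported with counts of members are FGF and ERK pathway targets, Notch pathway targets, clustered protocadherins, cytosolic ribosomal proteins, endoderm, extracellular matrix, forebrain and eye field, germline and methylation-sensitive, glia, hypoxia and glycolysis, integrated stress response and amino acid synthesis, midbrain and isthmus, naive pluripotency, neural progenitor, neuron, p53 targets, roof plate and cortical hem and surface ectoderm. Each was tested with camera at its preset correlation of 0.01, again with the correlation estimated from the data, and with fry, and adjusted over all lists of a comparison. Members were also adjusted over the list alone. Overlaps of calls were tested with Fisher's exact test among genes tested in both comparisons, and the expected number is n1 times n2 over N. For Z2KO and Z2HET, which share WT libraries, 20 simulated data sets without effects gave the correlation and covariance due to sharing. Their overlap of calls does not measure what sharing adds where genes change.

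Genes named in the report follow a rule written before the tests: the Zic genes in every comparison, the 6 largest higher and lower calls per comparison (10 for dTAG13 at 24 h and 48 h, 4 for Z3KO) with a mean of 5 CPM or more in the higher group, libraries that do not overlap and no predicted, clone or pseudogene symbol, up to 4 called members of each list with 3 or more calls and 1 member that did not pass, the 6 smallest adjusted p values per direction of each interaction, and the 8 largest mean changes per direction of each overlap. Some genes that qualify are left out for space.

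Libraries with the same number were checked for pairing by correlating their deviations from their group means. All pairs correlated over 0.1 in 2 of 11 comparisons, Z2KO over WT at day 0 (3 pairs, 0.284 to 0.716) and dTAG13 at 48 h (2 pairs, 0.184 and 0.239). With a replicate block 19 genes were called in the first and 4122 in the second. The labels do not describe pairs.

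The method was tested on simulated data with the design, depth and dispersion of some comparisons. These were Z2KO at days 0, 5 and 6, Z2HET over WT, dTAG13 at 48 h and 24 h, Z3KO and the interaction of days 5 and 3. In each, 67 genes were changed 1.5-fold, 67 genes 2-fold and 66 genes 4-fold, leaving out genes with few expected counts. Of 2-fold and 4-fold changes at day 5, 83.6% and 100.0% were called, and at day 6 94.0% and 95.5%. For Z2HET over WT they were 76.1% and 93.9%, for dTAG13 at 24 h 82.1% and 98.5%, and for Z3KO 29.9% and 74.2%. Of 1.5-fold changes 68.7% were called at day 5, 17.9% at day 0 and 2.99% in Z3KO. Genes left unchanged were called too, 20 of 14255 at day 6, 14 of 15353 for dTAG13 at 24 h and 2 to 11 in each of the others. For each comparison 1 data set was simulated. Alternatives were RLE scaling, library totals, no filter, a replicate block, leaving out each library, a fit of all 57 libraries, a fit of only the groups compared, and DESeq2 1.42.0. Figures were drawn with matplotlib 3.10.9.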

Results

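The data are RNA counts of 57 mouse E14Tg2a libraries in 18 groups. Stem cells (day 0) and cells at days 3, 5 and 6 of differentiation towards anterior neural progenitors were sequenced as wild type (WT) and as a Zic2 knockout (Z2KO), with 3 libraries per group at days 0 and 6 and 4 at days 3 and 5. A second differentiation supplied 3 day 6 libraries each of WT, Z2KO and a Zic2 heterozygote (Z2HET). Cells carrying a Zic2-FKBPV36 fusion were given dTAG13 or DMSO for the whole differentiation, the last 48 h or the last 24 h (3 libraries each, 2 for DMSO at 48 h). A Zic3 knockout (Z3KO) was sequenced at day 0 in 3 libraries. Library totals ranged from 12911654 to 46938618 counts. The tests measure spread between libraries, and the labels do not say whether libraries of a group came from separate cultures. Below, each gene is followed by its log2 fold change ± standard error, rose and fell refer to an adjusted p below 0.05, and levels in CPM (TMM-scaled) are means ± SD.

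What did WT cells do between day 0 and day 6? Between day 0 and day 6, naive pluripotency RNA fell (Tdgf1 -9.62 ± 0.15 and Zfp42 -8.59 ± 0.13) together with the germline gene Dazl -9.01 ± 0.21, and Zbtb16 8.88 ± 0.33, Ptn 8.43 ± 0.11, Fezf2 9.72 ± 0.35 and Six3 9.37 ± 0.26 rose. From day 3 to day 5 Sox21 5.98 ± 0.14, Hes5 4.50 ± 0.12 and Sox1 3.19 ± 0.09 rose. The naive pluripotency list gene Fgf4 -4.16 ± 0.12 and the FGF-responsive genes Etv4 -3.97 ± 0.12 and Etv5 -2.89 ± 0.08 fell. In the naive pluripotency list at day 6 over day 0, 0 of 18 genes rose, 18 fell and 0 did not pass (0 and 18 adjusted over the list alone). Jointly, naive pluripotency genes shifted downward by camera (adjusted p = 7.8e-67, adjusted p = 0.00172 with an estimated correlation). For the neural progenitor list in the same contrast, 16 of 18 genes rose, 2 fell and 0 did not pass (16 and 2 adjusted over the list alone). The neural progenitor genes together shifted upward by camera (adjusted p = 2.5e-14, adjusted p = 0.0129 with an estimated correlation). In the germline list, 0 of 20 genes rose, 20 fell and 0 did not pass (0 and 20 adjusted over the list alone). For germline and methylation-sensitive genes camera pointed downward (adjusted p = 7.2e-25, adjusted p = 0.0129 with an estimated correlation). At day 5 over day 3, among FGF and ERK pathway targets, 4 of 22 genes rose, 16 fell and 2 did not pass (4 and 16 adjusted over the list alone). The FGF and ERK pathway-target genes together shifted downward by camera (adjusted p = 6.0e-12, adjusted p = 0.00353 with an estimated correlation). In all, 11638 genes were called for day 6 over day 0 and 11500 for day 5 over day 3. Day 3 and day 5 libraries came from a different sequencing centre than those of days 0 and 6, so no contrast across those pairs of days was made.

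How much Zic RNA was present? Zic2 (ENSMUSG00000061524.8, chromosome 14, 122475435 to 122479852, mm10) stood at 114 ± 48.6 CPM in WT at day 0 (n = 3), 254 ± 11.9 at day 3 (n = 4), 172 ± 5.91 at day 5 (n = 4) and 109.8 ± 5.40 at day 6 (n = 3). Zic3 (ENSMUSG00000067860.11, chromosome X, 58022700 to 58041736) stood at 232 ± 17.4, 63.0 ± 3.02, 18.5 ± 2.06 and 11.7 ± 0.534 CPM on the same days, and Zic3 -4.40 ± 0.10 fell between day 0 and day 6. Days 3 and 5 were sequenced at another centre than days 0 and 6 and scaled in another fit. The levels therefore do not show a change between those pairs of days. Within the day 3 and 5 libraries Zic5 -2.43 ± 0.12, Zic3 -1.77 ± 0.09 and Zic2 -0.57 ± 0.10 fell in WT. In Z2KO the Zic2 RNA dropped at every day (Zic2 -5.76 ± 0.49 at day 0, Zic2 -4.55 ± 0.12 at day 3, Zic2 -5.49 ± 0.13 at day 5, Zic2 -6.62 ± 0.12 at day 6 and Zic2 -9.02 ± 0.46 in the second differentiation), while Z2HET held 117 ± 8.99 CPM against 192 ± 6.66 CPM in its WT (n = 3 each), a difference that did not pass (adjusted p = 0.138) although the libraries did not overlap, and that passed in a fit of only the 2 groups (adjusted p = 0.0129) and in one of all 57 libraries (adjusted p = 0.0390). In Z2KO of the second differentiation Zic2 ran from 0 to 1.03 CPM (scaled over all 57 libraries), so the size of that fold change is uncertain. Reads that remained on Zic2 in Z2KO, 10.9 ± 0.599 CPM at day 3, could not be assigned to exons from gene counts.

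**Figure D1:**
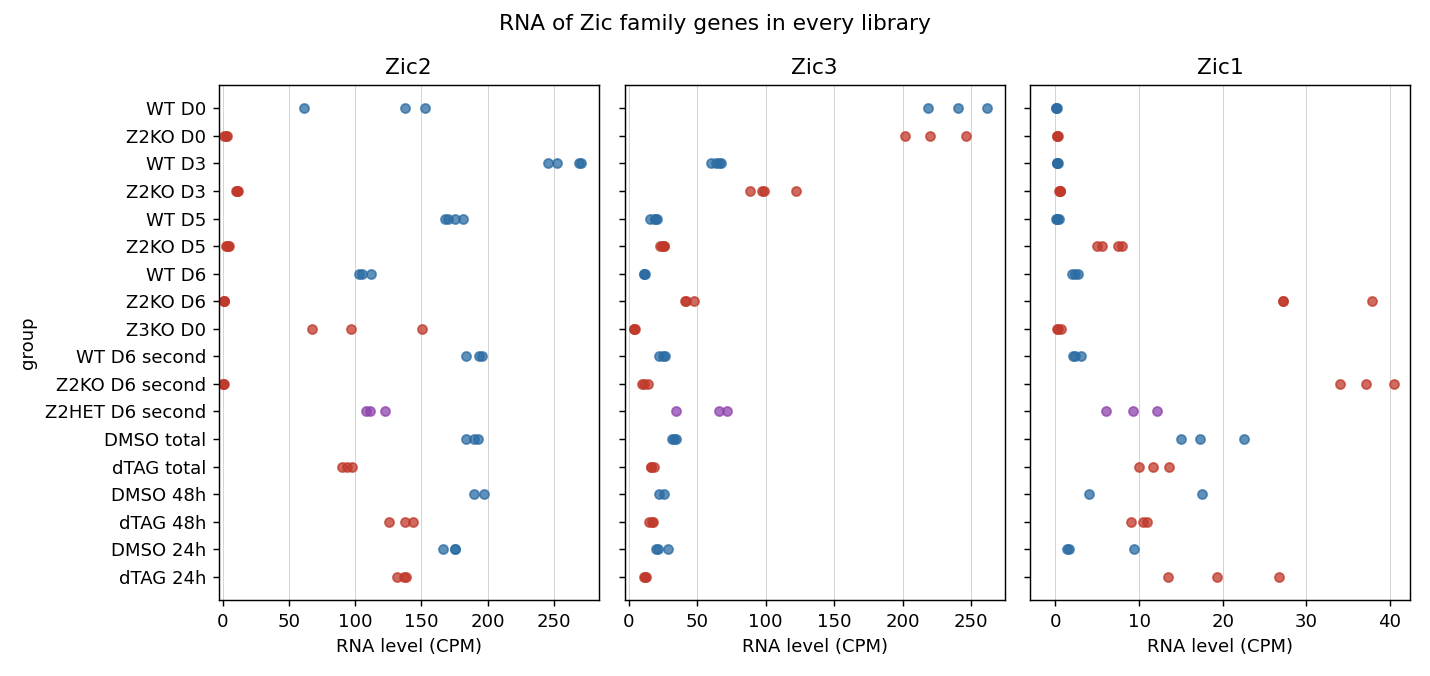
RNA of Zic2, Zic3 and Zic1 in every library, in CPM, by group. Red marks knockout and dTAG13 libraries, purple Z2HET, blue WT and DMSO.

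Did loss of Zic2 alter stem cells? At day 0 Zic2 itself fell, from 114 ± 48.6 to 2.11 ± 1.08 CPM (n = 3 each), and so did the X-linked gene Efhc2 -1.56 ± 0.15 (chromosome X, 17132049 to 17319368), from 35.8 ± 2.45 to 12.1 ± 1.48 CPM. edgeR called no gene higher. Zic5 (0.54 ± 0.17, adjusted p = 0.961) and Zic3 (-0.09 ± 0.11, adjusted p = 0.961) did not pass. Endoderm genes were shifted upward as a list although no member passed alone. In the endoderm list, 0 of 19 genes rose, 0 fell and 19 did not pass (13 and 0 adjusted over the list alone). Jointly, endoderm genes shifted upward by camera (adjusted p = 3.8e-33, adjusted p = 0.0357 with an estimated correlation). The germline list had 0 of 21 genes that rose, 0 that fell and 21 that did not pass (0 and 8 adjusted over the list alone). Camera placed germline and methylation-sensitive genes downward (adjusted p = 1.4e-17, adjusted p = 0.217 with an estimated correlation). Other lists passed camera at the preset correlation but not at the estimated one. They included cytosolic ribosomal proteins (7.6e-08, upward), mitochondrially encoded genes (1.9e-04, upward), histones (0.0013, upward), cholesterol synthesis (0.0024, downward) and mesoderm (0.0029, upward). Z2KO library 2 held 4.95% mitochondrial counts, and the other day 0 libraries of WT and Z2KO 2.52% to 3.10%. edgeR called 2 of 15552 genes, 0 higher and 2 lower, where 693 had an unadjusted p below 0.05 and DESeq2 called 46 (18 higher). With the replicate number as a block the count was 19 (5 higher), and 1727 genes had libraries that did not overlap (chance share 10%). Libraries of WT and Z2KO with the same number resembled each other at day 0 (correlations 0.284 to 0.716 over 3 pairs), and removing single libraries moved the count between 0 and 6 (Efhc2 and Zic2 lost their calls, Efhc2 in 5 and Zic2 in 3 of 6 runs). In simulated data of this size 53.7% of genes changed 2-fold and 90.9% of genes changed 4-fold were called, so smaller effects at day 0 could have been missed.

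What changed at day 3? Proneural and neuronal RNA rose in Z2KO, with Neurod4 6.93 ± 0.30, Onecut2 2.86 ± 0.20, Insm1 2.83 ± 0.10 and Neurod1 1.46 ± 0.14, and Neurod4 went from 0.0643 ± 0.0382 to 8.18 ± 0.682 CPM (n = 4 each). Notch pathway and progenitor genes rose as well (Dll1 1.65 ± 0.07, Lfng 1.61 ± 0.09, Vim 1.38 ± 0.06 and Sox2 0.99 ± 0.07), and so did Sp8 2.44 ± 0.18, En2 2.47 ± 0.15, Cnpy1 2.25 ± 0.18, Meis2 2.53 ± 0.13 and Nkx6-1 6.79 ± 0.25, while Lmx1b -1.34 ± 0.09 fell. Endoderm genes rose (Apob 4.45 ± 0.78, Ttr 4.18 ± 0.84 and Cxcr4 3.67 ± 0.14). Hypoxia and stress-response genes fell (Adm -2.24 ± 0.50, Ndufa4l2 -2.03 ± 0.27, Egln3 -1.84 ± 0.22, Ddit4 -1.17 ± 0.10 and Atf3 -1.04 ± 0.10), as did Slc5a5 -2.47 ± 0.09, Bhlhe40 -2.38 ± 0.28, Ier3 -2.26 ± 0.34, Cldn7 -1.13 ± 0.14 and Krt8 -0.73 ± 0.19. Zic5 1.15 ± 0.11, Zic3 0.67 ± 0.09 and Zic1 1.30 ± 0.35 rose.

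At day 3, in the neuron list, 17 of 24 genes rose, 3 fell and 4 did not pass (17 and 3 adjusted over the list alone). As a list, neuron genes shifted upward by camera (adjusted p = 7.6e-23, adjusted p = 0.0167 with an estimated correlation). For neural progenitors, 14 of 19 genes rose, 3 fell and 2 did not pass (14 and 3 adjusted over the list alone). Jointly, neural progenitor genes shifted upward by camera (adjusted p = 8.6e-13, adjusted p = 0.0385 with an estimated correlation). Among Notch pathway targets, 9 of 16 genes rose, 4 fell and 3 did not pass (9 and 4 adjusted over the list alone). As a list, Notch pathway-target genes shifted upward by camera (adjusted p = 4.2e-05, adjusted p = 0.0197 with an estimated correlation). The forebrain and eye field list had 14 of 25 genes that rose, 2 that fell and 9 that did not pass (16 and 2 adjusted over the list alone). Jointly, forebrain and eye field genes shifted upward by camera (adjusted p = 1.2e-06, adjusted p = 0.114 with an estimated correlation). Endoderm at day 3 had 14 of 23 genes that rose, 1 that fell and 8 that did not pass (17 and 1 adjusted over the list alone). For endoderm genes camera pointed upward (adjusted p = 9.7e-05, adjusted p = 0.471 with an estimated correlation). On the list of integrated stress response and amino acid synthesis, 2 of 21 genes rose, 16 fell and 3 did not pass (2 and 17 adjusted over the list alone). As a list, integrated stress response and amino acid synthesis genes shifted downward by camera (adjusted p = 3.6e-07, adjusted p = 0.212 with an estimated correlation). On the hypoxia and glycolysis list, 1 of 24 genes rose, 12 fell and 11 did not pass (1 and 14 adjusted over the list alone). The hypoxia and glycolysis genes together shifted downward by camera (adjusted p = 1.3e-04, adjusted p = 0.424 with an estimated correlation). edgeR called 6110 of 17757 genes, 3000 higher and 3110 lower, of which 610 and 635 changed 2-fold or more. The balance of higher and lower calls at day 3 depended on scaling, since 36.2% were higher under library totals and 49.1% under TMM.

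Did the effect grow by day 5? At day 5 neuronal RNA rose over almost the whole list, with Dcx 9.15 ± 0.31, Neurod4 7.24 ± 0.28 and Nhlh1 6.55 ± 0.13, and Dcx went from 0.127 ± 0.0803 to 75.9 ± 21.4 CPM (n = 4 each). Kcnk9 9.65 ± 0.28, St18 9.25 ± 0.38 and Lhx4 9.09 ± 0.27 rose too, Sst was 1523-fold higher (95% counting interval 521 to 7388) and Insm2 was at least 53.1-fold higher. Progenitor genes rose (Fabp7 4.47 ± 0.18, Pou3f2 4.34 ± 0.17, Pou3f3 3.94 ± 0.19 and Sox21 2.04 ± 0.09), with Notch genes (Dll4 3.42 ± 0.20, Lfng 1.98 ± 0.09, Nrarp 1.95 ± 0.09 and Jag1 1.67 ± 0.13) and the forebrain and eye genes Arx 6.83 ± 0.26, Vsx2 6.07 ± 0.28 and Emx2 2.87 ± 0.15. The eye field gene Hesx1 -2.40 ± 0.18 fell, and Rax (-0.44 ± 0.24, adjusted p = 0.136) did not pass. RNA of pluripotency and epithelial genes fell (Dppa5a -3.65 ± 0.20, Klf2 -1.95 ± 0.15, Nanog -1.93 ± 0.28, Esrp1 -3.17 ± 0.10, Epcam -2.76 ± 0.08 and Cdh1 -2.43 ± 0.07), as did Fgf5 -5.08 ± 0.20, the interferon-inducible GTPase genes Igtp -4.29 ± 0.19 and Irgm2 -4.14 ± 0.17, and the stress genes Nupr1 -4.04 ± 0.19, Trib3 -2.65 ± 0.18 and Chac1 -2.62 ± 0.25. Zic1 4.83 ± 0.27 and Zic3 0.43 ± 0.09 rose and Zic5 (0.26 ± 0.12, adjusted p = 0.0768) did not pass.

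At day 5, in the neuron list, 23 of 24 genes rose, 1 fell and 0 did not pass (23 and 1 adjusted over the list alone). The neuron genes together shifted upward by camera (adjusted p = 8.5e-54, adjusted p = 0.00158 with an estimated correlation). Neural progenitors at day 5 had 19 of 19 genes that rose, 0 that fell and 0 that did not pass (19 and 0 adjusted over the list alone). For neural progenitor genes camera pointed upward (adjusted p = 1.1e-14, adjusted p = 0.0201 with an estimated correlation). Notch pathway targets had 13 of 16 genes that rose, 2 that fell and 1 that did not pass (13 and 2 adjusted over the list alone). The Notch pathway-target genes together shifted upward by camera (adjusted p = 1.4e-07, adjusted p = 0.00239 with an estimated correlation). In surface ectoderm, 2 of 16 genes rose, 12 fell and 2 did not pass (2 and 12 adjusted over the list alone). As a list, surface ectoderm genes shifted downward by camera (adjusted p = 1.6e-12, adjusted p = 0.00203 with an estimated correlation). In naive pluripotency, 2 of 17 genes rose, 13 fell and 2 did not pass (2 and 13 adjusted over the list alone). For naive pluripotency genes camera pointed downward (adjusted p = 6.6e-06, adjusted p = 0.0903 with an estimated correlation). Integrated stress response and amino acid synthesis had 0 of 21 genes that rose, 20 that fell and 1 that did not pass (0 and 20 adjusted over the list alone). The integrated stress response and amino acid synthesis genes together shifted downward by camera (adjusted p = 1.4e-11, adjusted p = 0.0963 with an estimated correlation). Among clustered protocadherins, 31 of 41 genes rose, 2 fell and 8 did not pass (31 and 2 adjusted over the list alone). For clustered protocadherin genes camera pointed upward (adjusted p = 3.4e-06, adjusted p = 0.248 with an estimated correlation). edgeR called 9372 of 17757 genes, 4752 higher and 4620 lower (1636 and 1061 by 2-fold or more), and under library totals 64.8% rather than 50.7% of calls were higher.

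The knockout effect differed between day 5 and day 3. It was larger at day 5 for the neuronal genes Stmn2 2.37 ± 0.08, Nefm 3.65 ± 0.17 and Elavl4 2.98 ± 0.20 and for Add2 6.42 ± 0.23 and Cdh22 5.03 ± 0.19, and smaller for Neurog2 -4.21 ± 0.25. The difference was negative for Optn -3.32 ± 0.12, Prickle1 -2.47 ± 0.09 and Sgk1 -2.90 ± 0.11 and for the epithelial genes Epcam -2.37 ± 0.10 and Cdh1 -2.04 ± 0.09. Neurod4 (0.31 ± 0.80, adjusted p = 0.797) did not pass, so its rise was not shown to differ between the days. In this interaction the neuron list had 16 of 24 genes with a more positive effect, 5 with a more negative effect and 3 that did not pass (17 and 5 adjusted over the list alone). Jointly, neuron genes shifted upward by camera (adjusted p = 3.0e-18, adjusted p = 0.0299 with an estimated correlation). Surface ectoderm in the interaction had 2 of 16 genes with a more positive effect, 11 with a more negative effect and 3 that did not pass (2 and 11 adjusted over the list alone). The surface ectoderm genes together shifted downward by camera (adjusted p = 6.6e-11, adjusted p = 0.00419 with an estimated correlation). Naive pluripotency in the interaction had 0 of 17 genes with a more positive effect, 10 with a more negative effect and 7 that did not pass (0 and 10 adjusted over the list alone). Camera placed naive pluripotency genes downward (adjusted p = 1.7e-07, adjusted p = 0.0484 with an estimated correlation). The interaction called 6278 genes, with 73.8% positive under library totals against 49.7% under TMM.

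What was the state at day 6? All neuron genes rose, among them Dcx 9.32 ± 0.23, Neurod4 6.33 ± 0.20 and Nhlh1 5.73 ± 0.15, and Dcx went from 0.257 ± 0.312 to 159.9 ± 3.78 CPM (n = 3 each). Several genes went from none or almost none to clear expression, with Lhx4 1389-fold higher (95% counting interval 249 to 54910), St18 1245-fold higher (95% counting interval 223 to 49220), and Fstl5, Cartpt and Neurog1 at least 35.9-fold higher, at least 34.1-fold higher and at least 30.8-fold higher. Progenitor and Notch genes rose (Fabp7 6.43 ± 0.22, Pou3f2 3.70 ± 0.08, Hes5 2.75 ± 0.10, Dll4 4.65 ± 0.28 and Nrarp 1.78 ± 0.10). Forebrain and eye genes split, since Vsx2 7.24 ± 0.27 and Nr2e1 3.32 ± 0.35 rose and Rax -4.58 ± 0.28 and Hesx1 -3.58 ± 0.11 fell, Rax from 51.1 ± 13.2 to 2.11 ± 0.571 CPM. Bmp4 -5.23 ± 0.23, Matn1 -5.00 ± 0.35, Dppa5a -4.34 ± 0.26 and Sytl2 -4.25 ± 0.20 fell, as did Krt18 -2.62 ± 0.10, Krt8 -2.36 ± 0.09 and Cdh1 -2.23 ± 0.11 and p53 targets (Perp -1.35 ± 0.09, Phlda3 -1.10 ± 0.07 and Cdkn1a -0.69 ± 0.05). Zic1 3.74 ± 0.17 and Zic3 1.94 ± 0.09 rose, Zic4 was 42.5-fold higher (95% counting interval 11.4 to 356), and Zic5 (0.12 ± 0.08, adjusted p = 0.248) did not pass.

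The neuron list at day 6 had 24 of 24 genes that rose, 0 that fell and 0 that did not pass (24 and 0 adjusted over the list alone). For neuron genes camera pointed upward (adjusted p = 3.5e-77, adjusted p = 0.00846 with an estimated correlation). The neural progenitor list had 15 of 19 genes that rose, 0 that fell and 4 that did not pass (16 and 0 adjusted over the list alone). Camera placed neural progenitor genes upward (adjusted p = 3.0e-19, adjusted p = 0.0509 with an estimated correlation). Notch pathway targets at day 6 had 11 of 16 genes that rose, 3 that fell and 2 that did not pass (11 and 3 adjusted over the list alone). Jointly, Notch pathway-target genes shifted upward by camera (adjusted p = 8.4e-06, adjusted p = 0.0965 with an estimated correlation). Surface ectoderm at day 6 had 0 of 15 genes that rose, 13 that fell and 2 that did not pass (0 and 13 adjusted over the list alone). Jointly, surface ectoderm genes shifted downward by camera (adjusted p = 2.2e-13, adjusted p = 0.0602 with an estimated correlation). Forebrain and eye field at day 6 had 8 of 21 genes that rose, 9 that fell and 4 that did not pass (8 and 9 adjusted over the list alone). By camera, forebrain and eye field genes did not pass (adjusted p = 0.179, adjusted p = 0.694 with an estimated correlation). The mean of this last list was positive while its median and camera were negative. Among p53 targets, 0 of 20 genes rose, 16 fell and 4 did not pass (0 and 17 adjusted over the list alone). As a list, p53-target genes shifted downward by camera (adjusted p = 4.1e-05, adjusted p = 0.373 with an estimated correlation). Cytosolic ribosomal proteins had 0 of 75 genes that rose, 57 that fell and 18 that did not pass (0 and 61 adjusted over the list alone). Jointly, cytosolic ribosomal protein genes shifted downward by camera (adjusted p = 4.7e-06, adjusted p = 0.645 with an estimated correlation). Among them Rpl30 -0.61 ± 0.06 and Rpl34 -0.55 ± 0.08 fell. edgeR called 7740 of 14947 genes, 3953 higher and 3787 lower (1084 and 854 by 2-fold or more).

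Was the day 6 effect larger than that at day 0? The interaction of knockout and day was positive for Islr2 6.64 ± 0.27, Vgll3 6.22 ± 0.25, Elavl4 4.92 ± 0.21, Tubb2b 2.13 ± 0.11 and Nnat 2.71 ± 0.17 and negative for Dppa5a -4.38 ± 0.27, Krt8 -2.75 ± 0.18, Des -2.40 ± 0.17 and Lamb1 -2.13 ± 0.16. In the interaction of days 6 and 0 the neuron list had 20 of 24 genes with a more positive effect, 0 with a more negative effect and 4 that did not pass (21 and 0 adjusted over the list alone). Camera placed neuron genes upward (adjusted p = 1.7e-38, adjusted p = 3.2e-05 with an estimated correlation). In that test, naive pluripotency had 0 of 18 genes with a more positive effect, 9 with a more negative effect and 9 that did not pass (0 and 10 adjusted over the list alone). As a list, naive pluripotency genes shifted downward by camera (adjusted p = 1.1e-07, adjusted p = 0.00508 with an estimated correlation). In that test, endoderm had 0 of 19 genes with a more positive effect, 9 with a more negative effect and 10 that did not pass (0 and 10 adjusted over the list alone). Camera placed endoderm genes downward (adjusted p = 2.0e-07, adjusted p = 0.0190 with an estimated correlation). In that test, surface ectoderm had 0 of 17 genes with a more positive effect, 12 with a more negative effect and 5 that did not pass (0 and 13 adjusted over the list alone). For surface ectoderm genes camera pointed downward (adjusted p = 8.2e-16, adjusted p = 0.0124 with an estimated correlation). In all 2530 genes were called, and 1609 to 3720 with 1 library left out.

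Was the day 6 effect seen again in the second differentiation? The neuronal rise was present again, with Dcx 7.03 ± 0.32, Nhlh1 5.60 ± 0.18 and Neurod4 4.97 ± 0.34, and Kcnk9 8.14 ± 0.28 and Nhlh2 7.03 ± 0.35 rose with them. Fstl5, Lhx4, Cartpt and Sncg went from few counts or none to 5.59 ± 0.613, 22.2 ± 0.707, 6.83 ± 1.63 and 6.32 ± 1.30 CPM, that is at least 35.5-fold higher, 728-fold higher (95% counting interval 201 to 6022), 454-fold higher (95% counting interval 81.0 to 17960) and 209.5-fold higher (95% counting interval 57.6 to 1736). Forebrain genes rose (Nr2e1 6.97 ± 0.24, Vsx2 6.14 ± 0.57, Arx 5.30 ± 0.50 and Lhx5 2.55 ± 0.41), and Wnt3a -6.10 ± 0.78, Lmx1a -5.14 ± 0.81, Bmp4 -3.74 ± 0.51, Rspo1 -2.12 ± 0.25, En1 -4.30 ± 0.35 and Gbx2 -2.44 ± 0.50 fell. Slc13a4 -4.70 ± 0.34, Sytl2 -4.64 ± 0.34 and Fgf5 -4.53 ± 0.85 fell too. Genes of the p53 response rose (Plk2 1.18 ± 0.18, Cdkn1a 0.72 ± 0.08 and Phlda3 0.66 ± 0.09). Zic1 3.96 ± 0.24 rose and Zic3 -1.02 ± 0.28 fell, the latter call being lost with 1 library left out (Zic3 in 5 of 6 runs).

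In the second differentiation, in the neuron list, 24 of 24 genes rose, 0 fell and 0 did not pass (24 and 0 adjusted over the list alone). As a list, neuron genes shifted upward by camera (adjusted p = 1.2e-76, adjusted p = 0.0176 with an estimated correlation). Forebrain and eye field there had 10 of 22 genes that rose, 1 that fell and 11 that did not pass (11 and 1 adjusted over the list alone). Camera placed forebrain and eye field genes upward (adjusted p = 3.0e-05, adjusted p = 0.570 with an estimated correlation). Roof plate and cortical hem had 2 of 23 genes that rose, 12 that fell and 9 that did not pass (5 and 13 adjusted over the list alone). The roof plate and cortical hem genes together shifted downward by camera (adjusted p = 1.4e-04, adjusted p = 0.570 with an estimated correlation). The p53 targets had 13 of 20 genes that rose, 1 that fell and 6 that did not pass (14 and 1 adjusted over the list alone). The p53-target genes together shifted upward by camera (adjusted p = 1.3e-04, adjusted p = 0.570 with an estimated correlation). edgeR called 4055 of 15612 genes, 2246 higher and 1809 lower (937 and 438 by 2-fold or more), and 2575 to 2943 with 1 library left out. Across genes, the fold changes of the 2 day 6 experiments correlated (Spearman 0.616, genes not being independent replicates). Of the calls, 1626 genes were higher in both against 577.5 expected and 1271 lower in both against 447.1 expected.

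Where did the 2 day 6 experiments differ? The knockout effect was more positive in the second differentiation for the p53 targets Phlda3 1.76 ± 0.12, Plk2 1.61 ± 0.21, Cdkn1a 1.40 ± 0.10 and Perp 1.28 ± 0.19, for Ripk4 2.10 ± 0.11 and for the forebrain genes Fezf2 3.56 ± 0.67 and Six3 3.25 ± 0.33. It was more negative for the midbrain and isthmus list genes Gbx2 -2.82 ± 0.59, Irx1 -2.74 ± 0.28, En2 -2.40 ± 0.35 and En1 -2.21 ± 0.39, for Tnfrsf19 -1.88 ± 0.17 and for Zic3 -2.97 ± 0.34, which rose in the first differentiation and fell in the second. For the difference between differentiations, p53 targets had 15 of 20 genes with a more positive effect, 0 with a more negative effect and 5 that did not pass (16 and 0 adjusted over the list alone). Jointly, p53-target genes shifted upward by camera (adjusted p = 1.8e-32, adjusted p = 0.00775 with an estimated correlation). For the same difference, midbrain and isthmus had 2 of 20 genes with a more positive effect, 9 with a more negative effect and 9 that did not pass (2 and 10 adjusted over the list alone). Camera placed midbrain and isthmus genes downward (adjusted p = 1.2e-10, adjusted p = 0.0760 with an estimated correlation). The test called 1833 genes, and 1035 to 1605 with 1 library left out. Levels in WT differed between the experiments too, so these differences mix shifts of WT and of Z2KO. Scaled over all 57 libraries, Cdkn1a stood at 222 ± 3.48 CPM in the first WT and 116 ± 12.4 in the second. In Z2KO it stood at 137.5 ± 4.10 and 185.7 ± 11.8 CPM. Six3 stood at 67.7 and 21.8 CPM in WT and at 7.88 and 23.7 in Z2KO. En1 stood at 103 and 251.5 CPM in WT and at 24.1 and 12.4 in Z2KO.

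**Figure D2:**
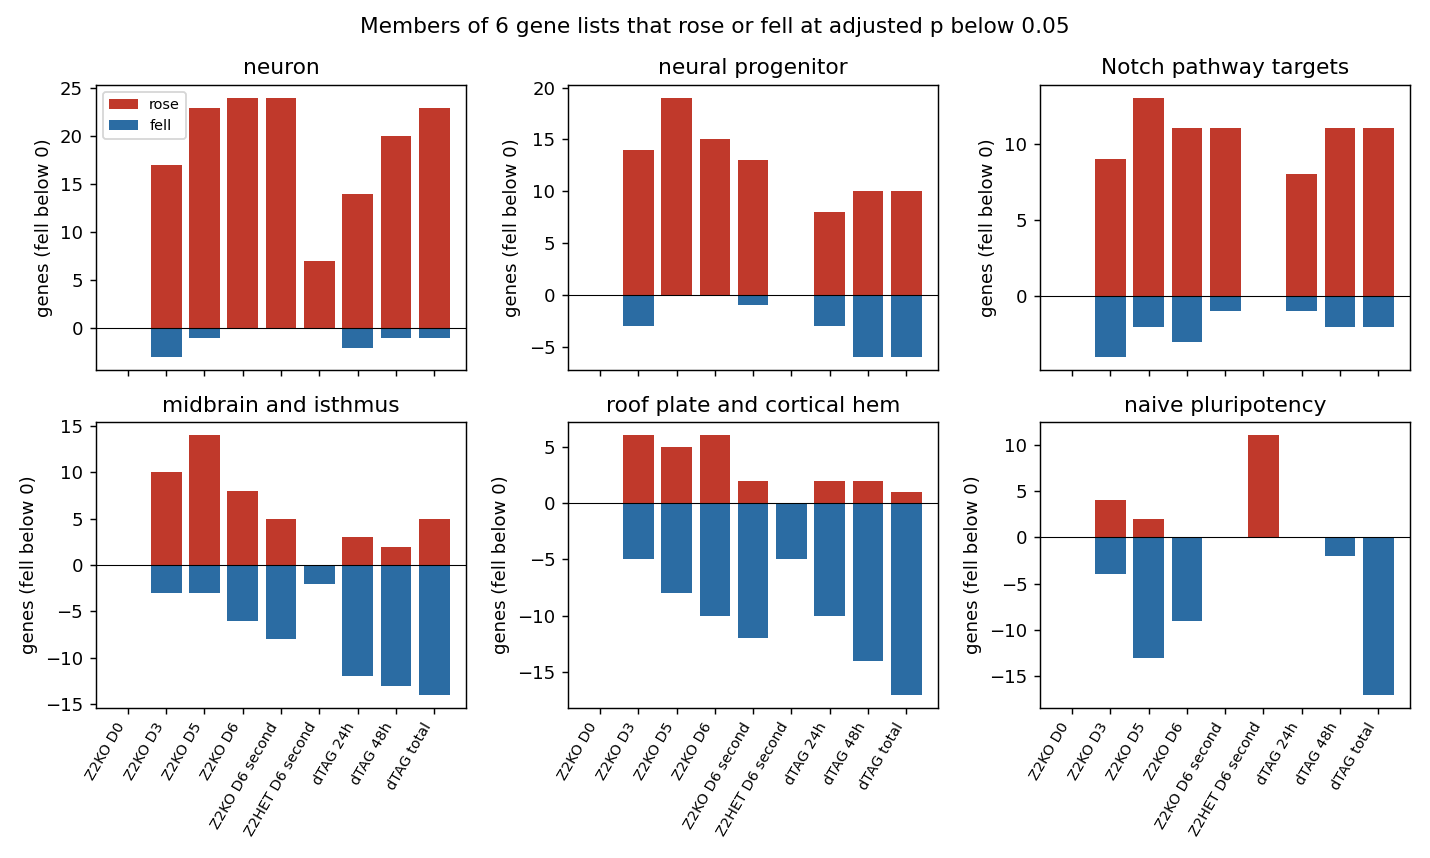
Members of 6 gene lists that rose (red) or fell (blue) at adjusted p below 0.05 in each comparison, as numbers of genes.

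What changed with 1 Zic2 allele? In Z2HET at day 6 the largest rises were in pluripotency genes, Tdgf1 4.62 ± 0.92, Nr5a2 4.54 ± 0.93, Dppa5a 4.41 ± 0.83, Esrrb 4.28 ± 0.86 and Tdh 3.97 ± 0.80, and Esrrb stood at 77.0, 6.46 and 51.5 CPM in libraries 1 to 3 against 1.97 to 2.80 CPM in WT. Neuronal genes rose (Neurod1 0.95 ± 0.18, Insm1 0.91 ± 0.21, Tubb3 0.89 ± 0.17 and Ina 0.69 ± 0.13). Adm -2.93 ± 0.35, Ankrd37 -1.55 ± 0.27, Dbx1 -2.30 ± 0.43, Calb2 -2.04 ± 0.27, Ier3 -2.26 ± 0.27, Sorcs3 -1.99 ± 0.41 and Ndrg1 -1.69 ± 0.16 fell, with the roof plate gene Rspo1 -1.21 ± 0.24. Zic1 1.92 ± 0.25 and Zic3 1.26 ± 0.27 rose, and Zic2 (-0.72 ± 0.25, adjusted p = 0.138) did not pass. In Z2HET, in the naive pluripotency list, 11 of 16 genes rose, 0 fell and 5 did not pass (16 and 0 adjusted over the list alone). The naive pluripotency genes together shifted upward by camera (adjusted p = 9.5e-14, adjusted p = 0.330 with an estimated correlation). Its neuron list had 7 of 24 genes that rose, 0 that fell and 17 that did not pass (17 and 3 adjusted over the list alone). The neuron genes together shifted upward by camera (adjusted p = 1.0e-09, adjusted p = 0.330 with an estimated correlation). Its roof plate list had 0 of 23 genes that rose, 5 that fell and 18 that did not pass (0 and 8 adjusted over the list alone). Jointly, roof plate and cortical hem genes shifted downward by camera (adjusted p = 2.7e-08, adjusted p = 0.330 with an estimated correlation). edgeR called 623 of 15612 genes, 382 higher and 241 lower, and the count ran from 51 to 3403 with 1 library left out. Calls of genes named here were lost with 1 library left out, Tdgf1, Nr5a2, Dppa5a, Esrrb, Tdh, Tubb3 and Zic3 in 5, Neurod1, Insm1, Ina, Dbx1, Sorcs3 and Rspo1 in 4, Ankrd37 in 3 and Zic1 in 1 of 6 runs.

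**Figure D3:**
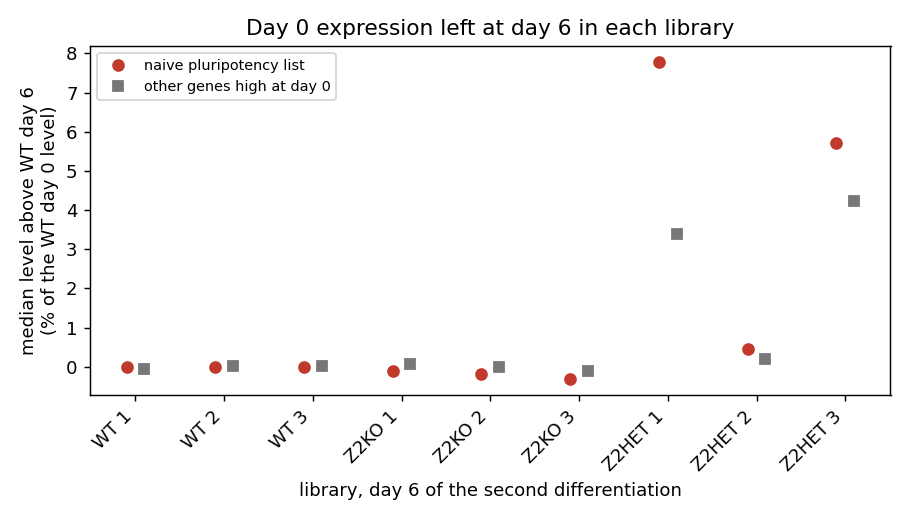
Median level above WT at day 6, in % of the WT day 0 level, for the naive pluripotency list and other genes high at day 0, in each library of the second differentiation.

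How did Z2HET compare with Z2KO? Against Z2KO, Z2HET held more Zic2 and En1 RNA (Zic2 8.30 ± 0.46 and En1 3.68 ± 0.35) and more pluripotency RNA (Tdgf1 6.94 ± 1.16, Fgf5 6.41 ± 0.80 and Dppa5a 6.21 ± 0.99), and less neuronal RNA (Dcx -4.65 ± 0.26, Nefm -3.44 ± 0.26 and Nhlh1 -3.35 ± 0.15), Nr2e1 -5.37 ± 0.21, Onecut3 -5.48 ± 0.21 and Sim2 -6.54 ± 0.46 and the Notch genes Dll4 -3.09 ± 0.23 and Hes5 -2.75 ± 0.32. In the neuron list, Z2HET over Z2KO had 0 of 24 genes that rose, 23 that fell and 1 that did not pass (0 and 24 adjusted over the list alone). Jointly, neuron genes shifted downward by camera (adjusted p = 2.7e-56, adjusted p = 0.0364 with an estimated correlation). In naive pluripotency it had 14 of 16 genes that rose, 0 that fell and 2 that did not pass (14 and 0 adjusted over the list alone). Jointly, naive pluripotency genes shifted upward by camera (adjusted p = 1.4e-07, adjusted p = 0.530 with an estimated correlation). The comparison called 4842 genes, 2320 higher and 2522 lower. Fold changes of Z2KO and Z2HET over the WT they shared correlated at Spearman 0.247, where simulation of no effect with the shared WT gave 0.441 (20 simulations), and their covariance was 0.139 against 0.0269 simulated. Higher in both were 146 genes (54.96 expected, adjusted p = 3.6e-31) and lower in both 136 (27.93 expected, adjusted p = 1.7e-64). Simulation gave 0.05 and 0, but without effects calls are rare, so it cannot show how far the shared WT raises these overlaps.

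What changed within 24 h of dTAG13? The largest falls were those of Wnt3a -7.46 ± 0.41, Grem1 -6.95 ± 0.42, Gdf10 -5.33 ± 0.48, Hes3 -5.09 ± 0.23, Nptx2 -4.61 ± 0.09, Sp5 -4.35 ± 0.27 and Cbln1 -4.04 ± 0.07, and Wnt3a went from 49.2 ± 13.7 to 0.279 ± 0.280 CPM (n = 3 each). The midbrain and isthmus list genes Gbx2 -3.52 ± 0.23, En1 -2.19 ± 0.19 and En2 -1.98 ± 0.26 fell, as did Lmx1a -2.46 ± 0.28 and Pax7 -2.63 ± 0.25. Gbx2 is also a member of the fixed list of hindbrain and spinal cord genes. Rises were led by Uncx 4.46 ± 0.21, Trh 3.97 ± 0.22, Plcl1 3.92 ± 0.41 and Sphk1 3.75 ± 0.26, and Trh went from 27.6 ± 8.91 to 429.7 ± 56.6 CPM. Proneural genes (Neurod4 3.19 ± 0.24, Neurog2 2.97 ± 0.27 and Nhlh1 2.48 ± 0.15) and forebrain genes (Nr2e1 3.50 ± 0.64, Arx 3.00 ± 0.59, Fezf2 2.84 ± 0.29 and Pax6 2.78 ± 0.37) rose too, although Arx did not pass in a fit of only the groups compared. Zic2 -0.35 ± 0.05, Zic3 -0.96 ± 0.11 and Zic5 -0.27 ± 0.07 fell. Zic1 2.26 ± 0.63 rose, although its 3 DMSO libraries were spread (4.21 ± 4.60 CPM) and its call was lost with 1 library left out (Zic1 in 4 of 6 runs). At 24 h, in the neuron list, 14 of 24 genes rose, 2 fell and 8 did not pass (16 and 3 adjusted over the list alone). For neuron genes camera pointed upward (adjusted p = 2.3e-18, adjusted p = 0.00881 with an estimated correlation). Midbrain and isthmus at 24 h had 3 of 20 genes that rose, 12 that fell and 5 that did not pass (3 and 12 adjusted over the list alone). As a list, midbrain and isthmus genes shifted downward by camera (adjusted p = 1.5e-11, adjusted p = 0.00881 with an estimated correlation). Roof plate and cortical hem at 24 h had 2 of 23 genes that rose, 10 that fell and 11 that did not pass (3 and 11 adjusted over the list alone). For roof plate and cortical hem genes camera pointed downward (adjusted p = 1.1e-04, adjusted p = 0.359 with an estimated correlation). Forebrain and eye field at 24 h had 12 of 24 genes that rose, 1 that fell and 11 that did not pass (13 and 1 adjusted over the list alone). As a list, forebrain and eye field genes shifted upward by camera (adjusted p = 5.2e-07, adjusted p = 0.359 with an estimated correlation). edgeR called 3401 of 16100 genes, 1695 higher and 1706 lower (264 and 485 by 2-fold or more), and 34.1% of calls were higher under library totals. A fit of only the groups compared called 1916 genes and one of all 57 libraries 1460.

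What changed over 48 h and over the whole differentiation? At 48 h Wnt3a -9.13 ± 0.48, Grem1 -8.04 ± 0.46, Hes3 -6.59 ± 0.28, Lmx1a -5.30 ± 0.37, Gbx2 -4.22 ± 0.26 and En1 -3.93 ± 0.23 fell, as did Nptx2 -4.62 ± 0.09 and Cbln1 -4.50 ± 0.08, and Gdf10 was 156-fold lower (95% counting interval 53.0 to 763). Rises included Olig2 5.50 ± 0.21, Neurod4 5.39 ± 0.27, Uncx 5.16 ± 0.19, Lhx3 5.11 ± 0.43 and Atoh7 4.85 ± 0.31, the Notch ligand Dll4 4.20 ± 0.28 and Trh 4.65 ± 0.27, from 20.9 ± 7.63 to 528 ± 46.8 CPM (n = 2 DMSO, 3 dTAG13). After the whole differentiation in dTAG13, Lhx3 7.37 ± 0.34, Atoh7 7.28 ± 0.25, Skor1 6.66 ± 0.38, Neurog2 4.58 ± 0.26, Neurod4 4.04 ± 0.18 and Dcx 3.85 ± 0.13 rose, and Lhx4 was 319.6-fold higher (95% counting interval 109 to 1553). Olig2 5.70 ± 0.13, a member of both the glia list and the fixed list of ventral patterning genes, rose. Wnt3a was 1986-fold lower (95% counting interval 549 to 16400), and Grem1 -6.84 ± 0.40, Lmx1a -6.27 ± 0.38, Pax8 -5.48 ± 0.20, En1 -4.82 ± 0.23 and Gbx2 -3.99 ± 0.22 fell, with the WNT target Axin2 -1.97 ± 0.08. Pluripotency RNA fell (Klf2 -1.79 ± 0.15 and Esrrb -1.72 ± 0.23), hypoxia genes rose (Ndufa4l2 3.19 ± 0.46, Vegfa 1.91 ± 0.15 and Bnip3 1.60 ± 0.31), Atf3 1.83 ± 0.30, Ddit4 1.46 ± 0.32 and Ddit3 1.04 ± 0.16 rose and Mcm4 -0.63 ± 0.06 and Mki67 -0.54 ± 0.07 fell. Zic2 RNA fell from 191 ± 4.29 to 95.2 ± 3.20 CPM (adjusted p = 9.6e-14), Zic5 -1.03 ± 0.07 and Zic3 -0.97 ± 0.11 fell, and Zic1 (-0.64 ± 0.55, adjusted p = 0.350) did not pass.

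At 48 h, in the neuron list, 20 of 24 genes rose, 1 fell and 3 did not pass (21 and 1 adjusted over the list alone). Camera placed neuron genes upward (adjusted p = 5.3e-52, adjusted p = 1.0e-04 with an estimated correlation). Midbrain and isthmus at 48 h had 2 of 20 genes that rose, 13 that fell and 5 that did not pass (4 and 13 adjusted over the list alone). The midbrain and isthmus genes together shifted downward by camera (adjusted p = 2.7e-20, adjusted p = 0.00167 with an estimated correlation). Notch pathway targets at 48 h had 11 of 15 genes that rose, 2 that fell and 2 that did not pass (12 and 2 adjusted over the list alone). For Notch pathway-target genes camera pointed upward (adjusted p = 2.9e-10, adjusted p = 0.0148 with an estimated correlation). Over the whole differentiation, the neuron list had 23 of 24 genes that rose, 1 that fell and 0 that did not pass (23 and 1 adjusted over the list alone). As a list, neuron genes shifted upward by camera (adjusted p = 2.8e-65, adjusted p = 2.7e-05 with an estimated correlation). For midbrain and isthmus there, 5 of 20 genes rose, 14 fell and 1 did not pass (5 and 14 adjusted over the list alone). Jointly, midbrain and isthmus genes shifted downward by camera (adjusted p = 2.8e-11, adjusted p = 0.0163 with an estimated correlation). For roof plate and cortical hem there, 1 of 23 genes rose, 17 fell and 5 did not pass (1 and 18 adjusted over the list alone). Camera placed roof plate and cortical hem genes downward (adjusted p = 1.1e-11, adjusted p = 0.0716 with an estimated correlation). For glia there, 5 of 7 genes rose, 2 fell and 0 did not pass (5 and 2 adjusted over the list alone). For glia genes camera pointed upward (adjusted p = 1.6e-04, adjusted p = 0.0163 with an estimated correlation). For hypoxia and glycolysis there, 22 of 24 genes rose, 0 fell and 2 did not pass (22 and 0 adjusted over the list alone). Jointly, hypoxia and glycolysis genes shifted upward by camera (adjusted p = 6.1e-05, adjusted p = 0.484 with an estimated correlation). For naive pluripotency there, 0 of 18 genes rose, 17 fell and 1 did not pass (0 and 17 adjusted over the list alone). For naive pluripotency genes camera pointed downward (adjusted p = 1.6e-04, adjusted p = 0.484 with an estimated correlation). edgeR called 4446 genes at 48 h (2261 higher, 2185 lower) and 8568 over the whole differentiation (4325 higher, 4243 lower) of 16100 tested. The 48 h contrast rests on 2 DMSO libraries and gave 2332 to 4010 calls with 1 library left out.

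Did time in dTAG13 matter? Whole-differentiation treatment exceeded 24 h for the neuronal genes Tubb3 2.02 ± 0.10, Nefm 3.18 ± 0.17, Kif5c 2.15 ± 0.10 and Stmn2 2.29 ± 0.20 and went further down for Pax8 -4.36 ± 0.26, Ccdc3 -4.43 ± 0.24 and Lmx1a -3.82 ± 0.56. Between 48 h and 24 h the effect grew for Tubb3 1.15 ± 0.11, Elavl3 1.77 ± 0.20 and Neurod4 2.20 ± 0.47 and sank for Pax8 -1.77 ± 0.21, Lmx1b -1.76 ± 0.17 and En1 -1.73 ± 0.29 (a call lost with 1 library left out for Neurod4 in 1 of 11 runs), and between the whole differentiation and 48 h it grew for Nefm 2.20 ± 0.18 and Kif5c 1.63 ± 0.10. For whole over 24 h, the neuron list had 19 of 24 genes with a more positive effect, 0 with a more negative effect and 5 that did not pass (20 and 0 adjusted over the list alone). The neuron genes together shifted upward by camera (adjusted p = 2.3e-35, adjusted p = 4.9e-04 with an estimated correlation). For 48 h over 24 h it had 14 of 24 genes with a more positive effect, 0 with a more negative effect and 10 that did not pass (18 and 0 adjusted over the list alone). Jointly, neuron genes shifted upward by camera (adjusted p = 1.1e-30, adjusted p = 9.9e-04 with an estimated correlation). In that test midbrain and isthmus had 1 of 20 genes with a more positive effect, 6 with a more negative effect and 13 that did not pass (1 and 8 adjusted over the list alone). For midbrain and isthmus genes camera pointed downward (adjusted p = 1.7e-09, adjusted p = 0.0333 with an estimated correlation). For whole over 48 h the neuron list had 13 of 24 genes with a more positive effect, 3 with a more negative effect and 8 that did not pass (14 and 3 adjusted over the list alone). For neuron genes camera pointed upward (adjusted p = 6.2e-12, adjusted p = 0.0480 with an estimated correlation). The tests called 4498, 316 and 1950 genes, and 3508 to 4884, 135 to 943 and 1063 to 1856 with 1 library left out. DMSO controls differed among themselves, with 2865 genes (1568 to 3385 with 1 library left out, 705 in a fit of all 57 libraries) called between the whole-differentiation and 24 h DMSO groups (Dcx 2.65 ± 0.21, Nhlh1 2.11 ± 0.16 and Insm1 1.67 ± 0.14), so each time point was compared with its own DMSO group.

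**Figure D4:**
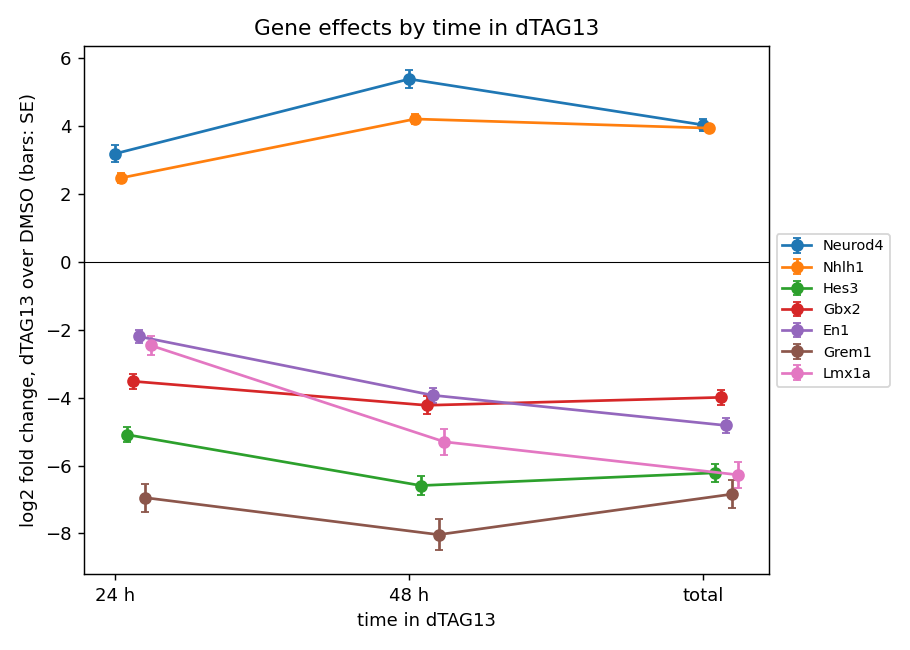
Log2 fold change of dTAG13 over DMSO by time in dTAG13 for 7 genes. Bars are standard errors.

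Did dTAG13 over the whole differentiation resemble the knockout? In both, neuronal genes rose, and Slc13a4 -6.24 ± 0.26 fell in dTAG13, but the effects differed for many genes. The knockout tested against dTAG13 here is that of the first day 6 experiment only. The dTAG13 effect was more negative than this knockout effect for the midbrain and isthmus list genes Pax8 -5.01 ± 0.28, Irx1 -4.76 ± 0.29, Gbx2 -4.37 ± 0.18 and En2 -3.38 ± 0.23 and the progenitor genes Fabp7 -5.49 ± 0.27, Pou3f3 -4.26 ± 0.14 and Ptn -3.38 ± 0.09, and for Sp8 -3.11 ± 0.10 and Cacna1g -3.54 ± 0.09. It was more positive for the forebrain genes Hesx1 5.53 ± 0.18, Foxd4 5.40 ± 0.15, Fezf2 4.25 ± 0.11 and Rax 5.06 ± 0.33 and for Ndufa4l2 4.98 ± 0.50 and Vegfa 1.88 ± 0.14. Levels in WT and DMSO differed too, so these differences mix shifts of the controls with those of Z2KO and dTAG13. Scaled over all 57 libraries, Hesx1 stood at 46.4 CPM in WT and 3.85 in Z2KO, and at 3.88 in DMSO and 15.2 in dTAG13. Fezf2 stood at 72.7 and 30.7, and at 13.8 and 111.9 CPM. In the second differentiation Hesx1 stood at 10.9 CPM in WT and 5.05 in Z2KO, and Fezf2 at 19.9 and 97.4. In this test midbrain and isthmus had 2 of 20 genes with a more positive effect, 15 with a more negative effect and 3 that did not pass (2 and 15 adjusted over the list alone). Camera placed midbrain and isthmus genes downward (adjusted p = 7.1e-14, adjusted p = 0.00847 with an estimated correlation). In this test neural progenitors had 2 of 19 genes with a more positive effect, 11 with a more negative effect and 6 that did not pass (2 and 11 adjusted over the list alone). As a list, neural progenitor genes shifted downward by camera (adjusted p = 2.8e-10, adjusted p = 0.00902 with an estimated correlation). The test called 8825 genes. The lines differ as well as the mode of loss, so the difference cannot be assigned to timing. Across 14829 genes the fold changes had a Spearman correlation of 0.0181 (Pearson 0.384) with the first day 6 knockout, and across 15332 genes one of 0.332 (Pearson 0.641) with the second (genes are not independent replicates). Of 4749 genes called in the first knockout and in dTAG13 over the whole differentiation, 2561 changed in opposite directions. Higher in both were 1234 genes (1074 expected, adjusted p = 2.6e-11) and lower in both 954 (1021 expected, adjusted p = 1.00). Among 2-fold calls 436 were higher in both (70.9 expected) and 183 lower in both (37.6 expected).

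Which genes moved the same way in several experiments? In both day 6 knockouts and all 3 dTAG13 durations, Neurod4 4.79, Islr2 4.75, Uncx 4.61, Nhlh1 4.39, Nr2e1 3.92 and Ebf3 3.63 rose and Sytl2 -3.96, En1 -3.47, Nptx2 -3.26 and Klhl14 -3.19 fell (mean log2 fold changes over the 5 comparisons), with Zic2 among the latter. Of 14730 genes 267 were higher in all 5 comparisons (2.59 expected if calls were independent) and 261 lower (1.86 expected). Higher in every Z2KO comparison from day 3 to day 6 were 590 of 14729 genes (31.8 expected), among them Neurod4 6.37, Ebf3 4.68, Nkx6-1 4.54 and Onecut2 3.95, and lower in every one were 507 (23.2 expected), among them Fgf5 -3.85, Esrp1 -2.26 and Car4 -2.24. All 3 dTAG13 durations shared 835 higher (63.9 expected) and 937 lower genes (61.0 expected) of 16100. Day 5 and day 6 knockout effects had a Spearman correlation of 0.797, day 3 and day 5 one of 0.352, 48 h and 24 h of dTAG13 one of 0.538, and the whole differentiation and 48 h one of 0.647. Higher in both 48 h and 24 h were 1028 genes (238.0 expected) and lower in both 1077 (231.5 expected). The second day 6 knockout and dTAG13 over the whole differentiation shared 1284 higher (594.9 expected, adjusted p = 9.0e-250) and 890 lower genes (481.4 expected, adjusted p = 6.8e-107). Overlaps were adjusted as a family of 42 tests. Genes of chromosome 15 were shifted downward in Z2KO over WT at day 3 (median log2 fold change -0.15, 29.2% of genes positive), day 5 (-0.13), day 6 (-0.12) and in the second differentiation (-0.09), but not at day 0 (0.04), and in Z2HET over WT the median was -0.05 (38.2% positive). Genes of chromosome 1 were shifted downward in Z2KO at day 3 (-0.10, 34.9% positive), day 5 (-0.09), day 6 (-0.09) and day 0 (-0.05), but not in the second differentiation (-0.01). At day 0 chromosome 1 did not stand out, since shifts of similar size were seen on X (-0.07), 18 (-0.05), 13 (-0.04) and 7 (0.07).

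What did loss of Zic3 do in stem cells? In Z3KO at day 0 Zic3 RNA fell (Zic3 -5.90 ± 0.15), from 228 ± 17.3 to 3.79 ± 0.442 CPM (n = 3 each), and Zic5 -0.87 ± 0.23 fell. Endoderm and extracellular matrix genes rose (Ttr 7.00 ± 1.07, Col4a1 4.18 ± 0.52, Foxa2 4.01 ± 0.36, Lama1 3.47 ± 0.25 and Thbs1 4.28 ± 0.86), with Krt18 4.64 ± 0.73, Krt8 4.04 ± 0.52 and Arsi 7.50 ± 0.73 and Gkn2, which was 865-fold higher (95% counting interval 296 to 4196). Germline genes (Dazl -2.67 ± 0.23 and Xlr3a -4.50 ± 0.84) and pluripotency genes (Prdm14 -1.44 ± 0.37 and Nanog -1.04 ± 0.26) fell, and so did Efhc2 -4.59 ± 0.69 and Fthl17f -5.46 ± 0.72. With 1 library left out calls were lost for Zic5 in 4, Nanog in 3 and Prdm14 in 2 of 6 runs. In the endoderm list of Z3KO, 16 of 22 genes rose, 0 fell and 6 did not pass (17 and 0 adjusted over the list alone). As a list, endoderm genes shifted upward by camera (adjusted p = 1.2e-19, adjusted p = 0.103 with an estimated correlation). The germline list in Z3KO had 2 of 21 genes that rose, 16 that fell and 3 that did not pass (2 and 16 adjusted over the list alone). As a list, germline and methylation-sensitive genes shifted downward by camera (adjusted p = 4.6e-10, adjusted p = 0.0704 with an estimated correlation). Extracellular matrix had 11 of 20 genes that rose, 0 that fell and 9 that did not pass (11 and 0 adjusted over the list alone). Camera placed extracellular matrix genes upward (adjusted p = 1.8e-05, adjusted p = 0.559 with an estimated correlation). Naive pluripotency in Z3KO had 0 of 18 genes that rose, 9 that fell and 9 that did not pass (1 and 9 adjusted over the list alone). Camera placed naive pluripotency genes downward (adjusted p = 0.0202, adjusted p = 0.837 with an estimated correlation). edgeR called 5573 of 16669 genes, 3016 higher and 2557 lower (1966 and 971 by 2-fold or more).

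The Z3KO libraries were sequenced at another centre than the WT libraries of day 0, so genotype and centre are confounded in this comparison. Of 344 tested genes 2-fold higher in every WT library of that centre (8 libraries of days 3 and 5) than in the 6 WT libraries of days 0 and 6, 326 were among the 1966 genes 2-fold higher in Z3KO and 1 was lower. Of 70 genes lower in every WT library of that centre, 64 were among the 971 lower in Z3KO and 0 were higher. Rpl17 (924 ± 114 CPM in WT at day 0, 55.5 ± 7.18 at day 3, 952 ± 54.2 at day 6 and 71.9 ± 12.2 in Z3KO) followed the centre, whereas Col4a1 (194.5 ± 15.7 CPM in WT at day 0, 164 ± 4.45 at day 3, 161 ± 11.0 at day 5, 135 ± 3.96 at day 6 and 3590 ± 2631 in Z3KO, where libraries stood far apart) did not. Genes of chromosome 15 were shifted upward in Z3KO libraries 1 and 2 but not in 3 (median log2 ratio 0.62, 0.69 and 0.03 over 451 genes), and 218 of the 3016 higher calls lie on that chromosome. Without chromosome 15, 5319 calls remained. RNA of 8 Y-linked genes also differed between libraries of a group, with 2217, 6607 and 0 counts in Z3KO libraries 1 to 3, 672, 249 and 0 in Z2HET and 1631, 560 and 2608 in Z2KO of the second differentiation. The labels do not say whether libraries of a group share a clone. Removing single libraries moved the count between 2510 and 8114.

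**Figure D5:**
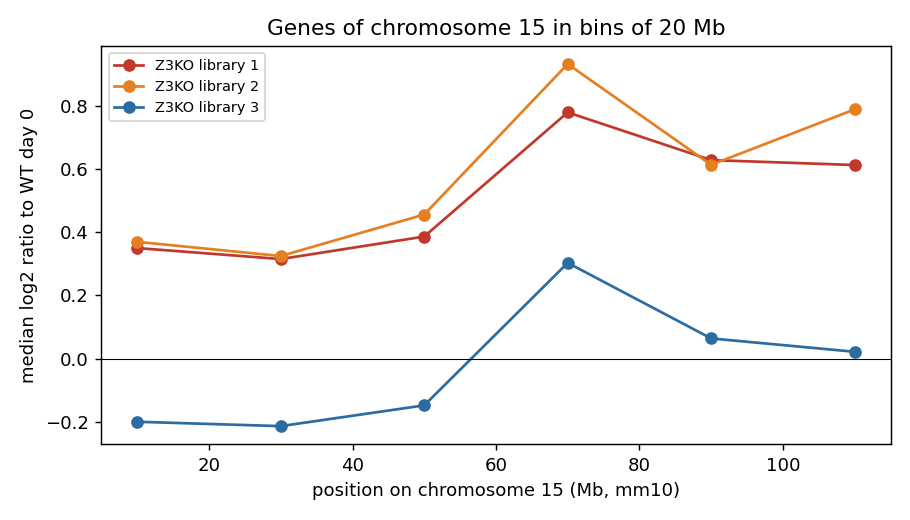
Median log2 ratio of each Z3KO library to WT at day 0 over genes of chromosome 15, in bins of 20 Mb.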

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

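The pairs of gene and group were tested with a gap ratio in groups of 4 libraries, and by chance such a test finds about 1 in 20 groups. Of 139 ratios 6 were high. They were Sst in WT day 5 (replicate 1 above the others, 1), Rax in WT day 5 (replicate 1 above, 0.834), Vim in Z2KO day 3 (replicate 1 below, 0.907), Sox2 in Z2KO day 3 (replicate 2 below, 0.983), Lmx1b in Z2KO day 3 (replicate 3 above, 0.852) and Esrp1 in Z2KO day 5 (replicate 1 above, 0.883).

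Effects differed between groups in every interaction. The Z2KO effect differed for 6278 genes between days 5 and 3, for 2530 between days 6 and 0 and for 1833 between the 2 differentiations at day 6. The dTAG13 effect differed for 1950 genes between the whole differentiation and 48 h, for 4498 between the whole differentiation and 24 h, and for 316 between 48 h and 24 h. The dTAG13 effect over the whole differentiation and the Z2KO effect at day 6 differed for 8825 genes.

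As lists, p53 targets (adjusted p = 1.76e-32) and midbrain and isthmus (adjusted p = 1.21e-10, but 0.0760 at the estimated correlation) differed between the differentiations. The neuron list differed between days 5 and 3 (adjusted p = 3.05e-18) and between the whole differentiation and 24 h in dTAG13 (adjusted p = 2.3e-35). Midbrain and isthmus differed between dTAG13 over the whole differentiation and Z2KO at day 6 (adjusted p = 7.06e-14).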

How the results depend on the processing

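Among the comparisons simulated with the depth and spread of the libraries, the lowest shares of 2-fold changes called were at day 0 and in Z3KO (53.7% and 29.9%). These libraries were not the shallowest. Scaling decides the balance of calls. Under library totals the share of higher calls was 36.2% instead of 49.1% at day 3, 64.8% instead of 50.7% at day 5, 34.1% instead of 49.8% at 24 h in dTAG13, and 73.8% instead of 49.7% for the interaction of days 5 and 3. The median log2 fold change of all genes moved to 0.10 at day 5 and to 0.17 in that interaction. RLE moved no count by over 1.5 times. Where a value moved, the cause was not tested.

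Counts of genes called that moved: DESeq2 gave 46 for Z2KO at day 0 and 1487 for Z2HET over WT. No low-count filter gave 24 for Z2KO at day 0 and 719 for 48 h over 24 h in dTAG13. All 57 libraries in one fit gave 85 for Z2KO at day 0, 1332 for Z2HET over WT, 2262 for dTAG13 at 48 h, 1460 at 24 h, 10757 for Z3KO and 705 between DMSO groups. Only the libraries of the groups compared gave 6984 for Z2KO in the second differentiation, 58 for Z2HET over WT, 3217 for Z2HET over Z2KO and 1916 for dTAG13 at 24 h. The replicate block gave 19 for Z2KO at day 0, 287 for Z2HET over WT and 3339 for Z3KO.

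With 1 library left out the count ran from 0 (without WT D0 replicate 2, Z2KO D0 replicate 1 or 2) to 6 (without Z2KO D0 replicate 3) for Z2KO at day 0, with 1 without WT D0 replicate 1 or 3. It ran from 2575 (without WT replicate 2) to 2943 for Z2KO in the second differentiation and from 51 (without WT replicate 2) to 3403 (without Z2HET replicate 2) for Z2HET over WT, with 61 and 80 without WT replicates 1 and 3 and 217 without Z2HET replicate 1. For dTAG13 at 48 h it ran from 2332 (without DMSO 48h replicate 2) to 4010, and for Z3KO from 2510 (without WT D0 replicate 2) to 8114 (without Z3KO replicate 3), with 2625 without WT D0 replicate 1 and 3334 without Z3KO replicate 2.

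Among interactions, leaving out 1 library gave 1609 (without WT D6 replicate 1) to 3720 (without Z2KO D0 replicate 3) for days 6 and 0. Between the differentiations it gave 1035 (without second WT replicate 3) to 1605, with 1172 without WT D6 replicate 1, 1211 without Z2KO D6 replicate 2, 1118 without second WT replicate 2 and 1184 without second Z2KO replicate 3. For the whole differentiation over 48 h it gave 1063 (without DMSO 48h replicate 1) to 1856, with 1278 without DMSO total replicate 2. For 48 h over 24 h it gave 135 (without DMSO 48h replicate 2) to 943 (without DMSO 24h replicate 3), with 587 without DMSO 48h replicate 1. Between DMSO groups it gave 1568 (without DMSO 24h replicate 2) to 3385, with 1683 and 1740 without DMSO total replicates 1 and 2. No other left-out library moved a count by over 1.5 times.

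Calls of named genes also moved with the fit. With only the groups compared, Tdgf1, Nr5a2, Dppa5a, Esrrb, Tdh, Neurod1, Insm1, Tubb3, Ina, Ankrd37, Dbx1, Calb2, Sorcs3, Rspo1 and Zic3 did not pass in Z2HET over WT, nor Zic1 and Arx at 24 h in dTAG13, while Zic2 in Z2HET and Zic1 over the whole differentiation in dTAG13 passed. Without the filter Tdgf1, Nr5a2, Dppa5a, Esrrb, Tdh, Tubb3, Dbx1 and Zic3 in Z2HET, Zic2 in Z2KO at day 0, Zic3 in Z2KO of the second differentiation and Thbs1 in Z3KO did not pass. With the block Tdgf1, Nr5a2, Dppa5a, Esrrb, Tdh and Zic3 in Z2HET, Zic3 in Z2KO of the second differentiation and Zic5 in Z3KO did not. In the fit of all 57 libraries Neurod1 in Z2HET, Phlda3 in Z2KO of the second differentiation, Zic1 in Z2KO at day 3 and Zic2 and Zic5 at 24 h in dTAG13 did not, and Zic2 in Z2HET passed. Zic5 in Z2KO at day 5 passed under library totals and without WT D5 replicate 3 or Z2KO D5 replicate 2.

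Of 68 list results given with counts of members, 38 kept their side of 0.05 with the estimated correlation and 64 under fry. The replicate block was run for 49 of them, of which 48 kept their side and forebrain and eye field in Z2KO at day 6 passed (adjusted p = 0.0263). That list also passed under fry (adjusted p = 0.04997). Under fry the germline list in Z2KO at day 0 (0.18) and the naive pluripotency (0.0651) and neuron lists (0.0616) in Z2HET did not pass. Overlap of lower calls was below expectation at all calls but above it among 2-fold calls for Z2KO at day 5 with dTAG13 over the whole differentiation (4.45 times) and at 48 h (3.53 times), and for Z2KO at day 6 with the same groups (4.86 and 4.7 times). On library totals 32 of 36 Zic2 and Zic3 levels moved by less than 1 SD of their group. The others were Zic2 in Z2KO day 3 (10.3 instead of 11.0 CPM), in DMSO 48 h (199.6 instead of 193.7) and in DMSO 24 h (177.5 instead of 172.5), and Zic3 in Z2KO day 5 (26.5 instead of 24.8). These levels are scaled by TMM over all 57 libraries, and so differ a little from those of the report. Alternatives chosen after seeing the data left 1 library in a group, so the spread came from the other groups and the calls of that group rest on 1 library. Without Z2HET replicates 1 and 3 there were 600 and 4297 calls for Z2HET over WT and over Z2KO, and Nr5a2 1.95, Neurod1 0.59, Tubb3 0.56, Ina 0.35, Adm -2.42, Ndrg1 -1.52, Rspo1 -0.73 and Zic3 0.48 (log2) did not pass in Z2HET over WT, while Tdgf1 1.75, Esrrb 1.43, Tdh 1.32 and Dppa5a did. Without Z3KO replicates 1 and 2 there were 4345 calls, and Zic5 -0.57 did not pass.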

Other observations

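The tests of remaining day 0 expression, of chromosome 15 bins and of GC content and gene length were chosen after the patterns had been seen, and their limits were written before the values were computed. The tests on Zic2 dose, on the sequencing centre and on day 5 were added after the first values were known.

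Z2HET libraries 1 and 3 kept naive pluripotency RNA at day 6, and library 2 kept less (a median excess over WT at day 6 of 0.455% of the WT day 0 level). A rise with falling Zic2 dose is an unlikely cause, because Z2KO holds less Zic2 RNA than Z2HET and also less of this RNA. In Z2HET over Z2KO 14 of 16 list genes were higher and 0 lower, with a median log2 fold change of 4.55. Against WT the median in Z2KO was -1.30 with no gene passing. A rise at an intermediate dose alone was not tested. Undifferentiated stem cells left in the cultures could be the cause. Other genes high at day 0 exceeded WT at day 6 by a median of 3.38% of their WT day 0 level in library 1 and 4.23% in library 3. For the list these excesses were 7.79% and 5.72%. The ratios were 0.434 and 0.739, which lie on both sides of the limit of 0.5, so this cause stays open. Of 198 such genes, 92.4% and 91.9% were above the WT mean.

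Z3KO libraries 1 and 2 carried higher RNA over all of chromosome 15. An extra copy of the chromosome in most cells is a likely source, since the lowest median log2 shift of any 20 Mb bin was 0.314 with every bin shifted upward. The sequencing centre is an unlikely source, because library 3 from the same centre had a median shift of 0.0349. Copy number itself was not measured.

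Over all genes the fold changes of Z2KO at day 6 and dTAG13 over the whole differentiation had a rank correlation near 0 (0.0181), while Pearson was 0.384 and 436 genes were 2-fold higher in both (70.9 expected). Trends with GC content and gene length are unlikely to hide a rank correlation, since the correlation was 0.0596 after they were removed. A fault confined to the first day 6 libraries is an unlikely cause, because Z2KO at day 5 had a correlation of 0.0126 with dTAG13. The day 5 value cannot exclude a trait that days 5 and 6 share, since their knockout effects had a Spearman correlation of 0.797. The second day 6 knockout, of the same genotype, had a correlation of 0.332. The labels do not say whether the 2 knockouts are the same line. The knockout effect itself differed between the 2 differentiations for 1833 genes. How far this, a difference between lines or the stage of loss accounts for the low correlation was not tested and stays open.

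Libraries were also regrouped at random to see how often as many genes are called. For groups of 4, each of 35 splits was run. Only the real one (1) gave as many calls at day 3 (highest other 0), for WT day 5 over day 3 (highest other 0) and at day 5. A share of 1 in 35 makes chance unlikely there if libraries of a group are independent. The labels do not say whether they are. At day 5 another split called 1716 genes, which points to structure among those libraries. Groups of 3 allow 10 splits, too few for a share under 0.05. There, only the real split (1) gave as many calls for Z2KO at day 0, Z2KO at day 6, Z2KO in the second differentiation, Z2HET over WT, Z2HET over Z2KO, dTAG13 over the whole differentiation, Z3KO, WT day 6 over day 0 and the DMSO groups (highest other 0 in each), and for dTAG13 at 24 h (highest other 1). The 48 h contrast has 2 DMSO libraries and was not split.

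For interactions 40 splits were drawn. As many calls came from 1 split for days 5 and 3 (highest other 4710) and for dTAG13 against Z2KO (3032), the real one. From 2 splits each they came for days 6 and 0 (3585), between the differentiations (2804) and for the whole differentiation over 24 h (6046). Those other splits kept the real groups in 1 of the contrasts, and splits without a real contrast called 0 genes, or 1 for dTAG13 against Z2KO.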
